A study of Mus musculus with 12 samples.

How the data were processed

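RNA was sequenced from 12 libraries of 6 mouse liver cancer cell lines. Lines T1, T2 and T3 came from primary liver tumours and lines M1, M2 and M3 from lymph node metastases. The labels give BRAF V600E and loss of p53 for these lines, while the design text of the series names hepatocyte-specific BRAF V600E with deletion of either Trp53 or Cdkn2a. Each line gave 1 library after DMSO, the solvent, and 1 after 2 µM PLX4720, a BRAF inhibitor, both at 48 h. Replicates are therefore separate cell lines, 3 per site. The labels do not say whether lines share an animal, and the names of the deposited tables give T3, M2 and M3 a common number, so the independence of these 3 lines is not known.

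Per the labels' protocols, stranded total RNA libraries were made after removal of ribosomal RNA. Per the file headers, the deposited values are raw counts of fragments per gene, made by the authors with featureCounts 1.5.2 from exons of the Ensembl 84 annotation of GRCm38, for read pairs with both ends mapped. The recorded command holds no strand option, so overlapping genes on opposite strands cannot be told apart. The aligner is not given in the sources used here. Fragments shared between near-identical copies of a gene are counted as the authors' settings assigned them. Each table lists 47729 genes, of which 47224 were matched to a symbol of the reference annotation, and no line that names no gene. Totals ran from 31992512 to 39288748 counted fragments per library. Floors for groups at 0 fragments cover counting error only, since these reads carry no molecular identifiers. SDs are taken between lines. SEs were computed as the absolute fitted log2 change divided by the root of the F statistic of the edgeR test. The fitted change is shrunk by a prior count, so for genes with few fragments these SEs are approximate and can be too small.

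Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr and library sizes scaled by TMM, and the quasi-likelihood test was used with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. For PLX4720 against DMSO, all 12 libraries entered 1 fit of 16555 genes, with the cell line as a block and a treatment term for each site, which left 4 residual degrees of freedom. The effect over all 6 lines is the mean of both treatment terms, and the difference between sites was tested as an interaction contrast. Metastasis lines were compared with primary lines on the 6 libraries of each treatment, with 4 residual degrees of freedom and no block. The block comes from the cell line named in the labels: deviations from the group means correlated at 0.794 to 0.900 between both libraries of a line. Replicate numbers do not pair primary with metastasis lines, whose deviations correlated at -0.0881 to 0.0143. Libraries of a group were compared for duplicates, and each pair differed by more than counting noise, with a chi-square per degree of freedom of 127 at the least. CPM values printed are library-scaled counts computed here from the deposited counts with TMM factors, and changes per line are differences of log2(CPM + 1). An exact two-sided sign-flip permutation test over 64 patterns was run for the Tgfb genes.

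There were 33 gene lists, fixed from textbook knowledge before the data were examined, as were the design, the alternatives and the rule for naming genes. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with a correlation estimated per list, and with fry, each adjusted over the lists. Counts of members are out of those tested in a comparison. For some lists, such as the hepatocyte and the fibroblast and stellate ones, many members were not tested. Some lists share members: Tgfb2 is on the YAP/TAZ list too, and Ltbp2, Col1a1 and Fgfr2 each stand on more than 1 list. The naming rule always takes Tgfb1, Tgfb2, Tgfb3, Trp53, Cdkn2a and Braf. It also takes the largest changes in each direction of each comparison among genes past the threshold that have a given name, a mean log2 CPM of at least 1, and the same direction in every line (treatment) or no overlap between groups (site and interaction). From each gene list it takes up to 4 members with the smallest p. Among those list members, the ones printed were picked after their values were seen. Genes named outside the rule are said to be so, and a few single genes are not reported here.

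Each fit was tested on simulated counts in which 200 genes were changed. The changed genes were drawn only from those above a minimum mean count. Each gene had the same baseline in every library, without the differences between lines and sites of the real data. The rates below therefore do not cover genes with few fragments or genes near 0 in 1 site. For true log2 changes of 1 and 2, the fit recovered 98% and 100% over all 6 lines, 84% and 100% in primary lines, 86% and 100% in metastasis lines, and 52% and 97% for the difference between sites. False calls made up 7.48%, 4.17%, 4.62% and 6.88% of the calls, so the share over all 6 lines and for the difference exceeded the nominal level. For the site comparisons the same simulation recovered 0% at both sizes under DMSO, and 0% and 1% under PLX4720. After that result was seen, a second simulation with added sizes was run: for log2 changes of 1, 2, 4 and 6 it recovered 4%, 42%, 82% and 92% under DMSO and 0%, 28%, 88% and 94% under PLX4720. The site comparisons therefore have little power for log2 differences of 2 or less.

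Alternatives covered DESeq2 1.42.0, limma-voom, DESeq2's size factors in edgeR, no filter or a stricter one, removal of mitochondrial and small RNA genes, the fits without or with a block, each site fitted alone, a random line effect, a fold-change threshold, and each line left out in turn. Further ones left out or joined M2 and M3, whose deposited tables share with those of T3 a number that the labels do not explain. Figures were drawn with matplotlib.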

Results

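The series asks how BRAF inhibition affects Tgfb2 and metastasis in mouse liver cancer driven by BRAF V600E. Counts of fragments per gene were available for 3 primary tumour lines (T1 to T3) and 3 lymph node metastasis lines (M1 to M3), each with 1 DMSO and 1 PLX4720 library. Library totals were 31992512 to 39288748 fragments. Mitochondrial genes took 3.68% of the fragments of T3 with PLX4720, and 0.189% to 0.712% in the other 11 libraries.

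Transcripts of the genes named in the design were measured in every library. Trp53 (chromosome 11, 69580359 to 69591873, GRCm38), a tumour suppressor that the labels give as lost, stood at 2.79 to 8.55 CPM, and no library known to keep the gene was analysed here, so its loss was not tested. Cdkn2a (chromosome 4, 89274471 to 89294653), which encodes the p16 and Arf tumour suppressors, stood at 79.2 to 254 CPM in T1, T2, T3 and M3. In M1 and M2 it stood at 0 to 0.466 CPM, on 0 to 17 fragments per library. Braf rose with PLX4720 over all 6 lines by a log2 change of 0.36 ± 0.10 (SE; edgeR adjusted p = 0.0254), with 0.11 ± 0.14 in primary lines (adjusted p = 0.671), 0.61 ± 0.14 in metastasis lines (adjusted p = 0.0148) and a difference of 0.50 ± 0.19 that did not pass (adjusted p = 0.26). Over all 6 lines the change of Braf missed the threshold without T2, T3 or M2 (edgeR adjusted p = 0.0522, 0.0581 and 0.0831), and in metastasis lines without M2 or M3 (adjusted p = 0.1 and 0.0518). Neither Trp53 (-0.08 ± 0.13, edgeR adjusted p = 0.705) nor Cdkn2a (0.19 ± 0.16, adjusted p = 0.417) passed the threshold, though without M3 the change of Cdkn2a was 1.03 (adjusted p = 0.0346), with its metastasis part on at most 17 fragments per library.

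Site of origin separated the libraries more than treatment. The first principal component held 62.0% of the variance and parted primary from metastasis lines, and the second held 9.44%. Log2 CPM correlated across genes at 0.975 to 0.989 between both libraries of a line, 0.917 to 0.960 between lines of a site and 0.775 to 0.835 between sites.

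**Figure D1:**
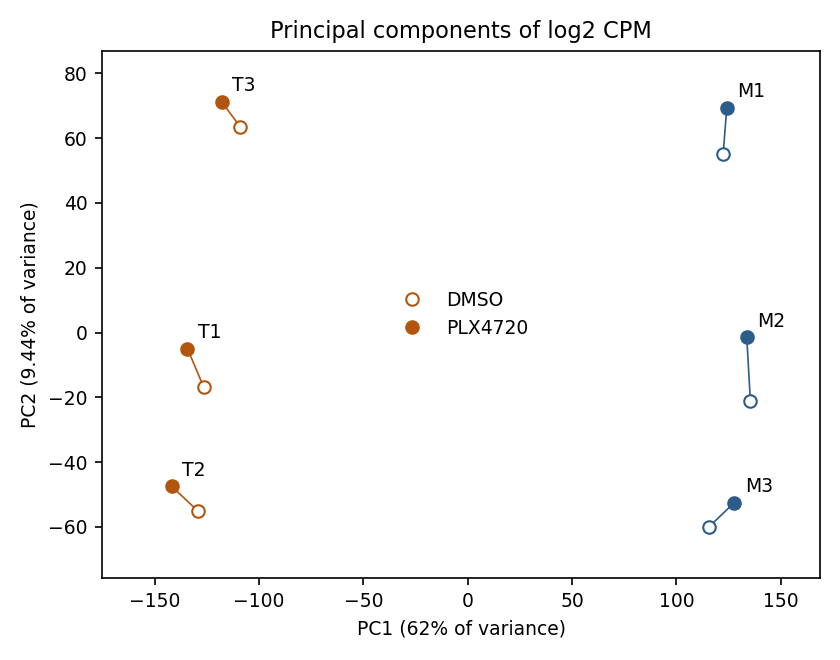
Each point is a library on the first (horizontal) and second (vertical) principal components of log2 CPM, in the units of the component scores, with open points for DMSO, filled points for PLX4720, orange for primary and blue for metastasis lines. Primary lines lie at negative and metastasis lines at positive values of the first component, which holds 62.0% of the variance.

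Tgfb2, the ligand named in the title of the series, rose in all 6 lines. Its level (gene ENSMUSG00000039239, chromosome 1, 186622792 to 186705989, minus strand) went from 2.53 ± 0.439 to 16.1 ± 2.86 CPM in primary lines and from 2.83 ± 0.132 to 21.4 ± 3.00 CPM in metastasis lines (mean ± SD, n = 3 lines each). The fitted increase was 6.91-fold, a log2 change of 2.79 ± 0.14 (SE; edgeR adjusted p = 2.46e-05). The exact sign-flip permutation test over the 6 lines gave p = 0.0312, the smallest it allows. Tgfb3 also rose in 6 of 6 lines, by 1.32 ± 0.13 (edgeR adjusted p = 0.00035; exact permutation p = 0.0312), from 18.3 ± 18.2 to 54.4 ± 55.9 CPM in primary lines (mean ± SD, n = 3). Tgfb1 was higher in 2 of 6 lines, with a log2 change of -0.30 ± 0.20 (edgeR adjusted p = 0.307; exact permutation p = 0.25). Without M1 the change of Tgfb1 was -0.57 and passed (edgeR adjusted p = 0.0214). The increase of Tgfb2 was 2.66 in primary and 2.91 in metastasis lines, and the difference of 0.25 ± 0.26 did not pass the threshold (edgeR adjusted p = 0.768).

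**Figure D2:**
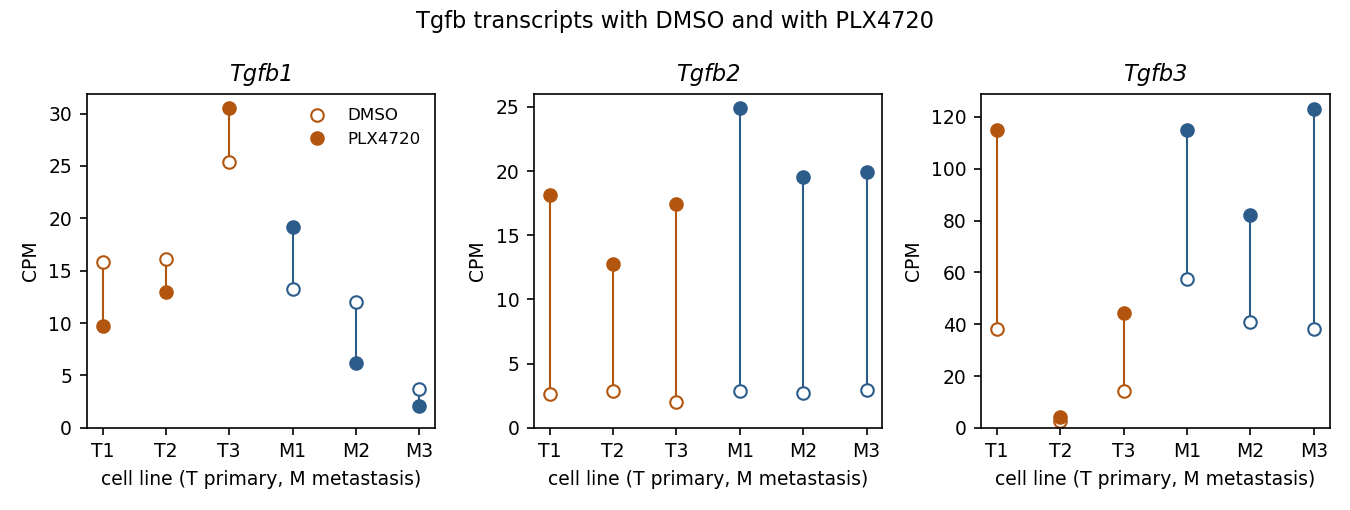
Levels of Tgfb1, Tgfb2 and Tgfb3 in CPM (vertical) for each cell line (horizontal), with open points for DMSO, filled points for PLX4720, orange for primary and blue for metastasis lines; a line joins both libraries of a cell line. Tgfb2 and Tgfb3 are higher with PLX4720 in 6 of 6 lines and Tgfb1 in 2 of 6.

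PLX4720 against DMSO over all 6 lines asks what the inhibitor changes in cells of either origin. Its values are means of both sites' treatment terms, so some of them rest mostly on 1 site. Transcripts that report ERK signalling fell, and those of the EGF receptor ligands Areg and Btc fell with them. Etv4, an ERK-induced transcription factor, was 4.43-fold lower (log2 change -2.15 ± 0.16, edgeR adjusted p = 0.000124), and the feedback inhibitors Spred3 and Spred1 fell by 1.17 and 0.85 on the log2 scale. Of 20 ERK output genes 13 fell and 3 rose, with 13 and 3 adjusted over the list alone (camera adjusted p = 3.72e-09; adjusted p = 0.332 with an estimated correlation). Those that rose were Spry1 (0.55 ± 0.07), a feedback inhibitor, and, named after their values were seen, Egr1 (1.62 ± 0.49), an immediate early transcription factor, and Epha4 (1.13 ± 0.25), an ephrin receptor whose changes per line ran from -0.30 in T2 to 2.79 in M2. Areg and Btc, both ligands of the EGF receptor, were 9.04-fold and 7.56-fold lower (edgeR adjusted p = 0.000223 and 2.73e-05). Nrg1, a ligand of the ERBB receptors, rose by 1.27 ± 0.10, and Igf1 by 3.38 ± 0.24, with 7 fragments over the metastasis DMSO libraries. Of 18 ligand genes tested 6 rose and 4 fell, with 6 and 4 adjusted over the list alone (camera adjusted p = 0.912).

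Receptor tyrosine kinases rose more often than they fell. Of 18 tested, 7 rose and 1 fell, with 7 and 1 adjusted over the list alone (camera adjusted p = 0.0188; adjusted p = 0.540 with an estimated correlation). Fgfr2 rose by 1.56 ± 0.21, Egfr by 0.93 ± 0.10 and the collagen receptor Ddr1 by 0.84 ± 0.08, and Mertk fell by 1.48 on the log2 scale (edgeR adjusted p = 0.0014, 0.00046, 0.000263 and 0.00713). Without T3 or M1 the list did not pass (camera adjusted p = 0.130 and 0.0892).

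Many members of the TGF-β lists rose. Among 23 ligand, receptor and activator genes 12 rose and none fell, with 13 and 1 adjusted over the list alone (camera adjusted p = 3.54e-05; adjusted p = 0.389 with an estimated correlation). Itgb8, an integrin chain that releases latent TGF-β, rose 2.82-fold (edgeR adjusted p = 0.00223). Itgb6, another, passed as well (adjusted p = 0.00148), with its fold left out here for 3 fragments over the metastasis DMSO libraries. Among 24 target genes 18 rose and 2 fell, with 20 and 2 adjusted over the list alone (camera adjusted p = 1.22e-11; adjusted p = 0.269 with an estimated correlation). The inhibitory Smad6 rose by 1.44 ± 0.12, Id3 by 0.69 ± 0.06 and Id2 by 0.70 ± 0.07, and the co-repressor Tgif1 fell by 0.58 on the log2 scale. YAP/TAZ targets, a list that holds Tgfb2 itself, had 14 of 23 members higher and none lower, with 14 and 1 adjusted over the list alone (camera adjusted p = 2.21e-10; adjusted p = 0.269 with an estimated correlation). Ccn1 and Amotl2 rose by 1.55 ± 0.08 and 1.48 ± 0.08. Mesenchymal genes rose in 8 and fell in 1 of 22 cases, with 10 and 1 adjusted over the list alone (camera adjusted p = 0.0188; adjusted p = 0.595 with an estimated correlation). Without T3 or M1 this list did not pass (camera adjusted p = 0.170 and 0.0743).

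Transcripts of the interferon response rose in 19 of 22 cases and none fell, with 19 adjusted over the list alone. This was the only list past the threshold both with the preset correlation (camera adjusted p = 5.96e-15) and with an estimated one (adjusted p = 0.0271). Ifit3 rose 3.34-fold, the transcription factor Stat2 2.34-fold, and the RNA sensors Ddx58 and Ifih1 2.06-fold and 1.83-fold (edgeR adjusted p = 0.000356, 0.000197, 0.000177 and 0.000254). These means rest mostly on the metastasis lines, where most members of the list passed, while few passed in primary lines alone. The log2 changes of Ifit3, Stat2 and Ifih1 were 0.62, 0.62 and 0.45 in primary and 2.86, 1.84 and 1.29 in metastasis lines. Antigen presentation genes rose in 10 of 13 cases, with 11 adjusted over the list alone (camera adjusted p = 7.40e-06; adjusted p = 0.269 with an estimated correlation), among them Tapbp (1.06 ± 0.09) and Psmb9, an immunoproteasome subunit whose fold is left out for 3 fragments over the primary DMSO libraries. Cytokine and NF-κB genes rose in 14 and fell in 1 of 20 cases, with 15 and 1 adjusted over the list alone (camera adjusted p = 2.24e-07; adjusted p = 0.332 with an estimated correlation). The chemokines Cxcl5 and Cxcl1 rose by 1.91 ± 0.17 and 1.40 ± 0.11, and the alarmin Il33 fell by 1.69 on the log2 scale. The adhesion molecule Icam1 rose by 3.03 ± 0.29, with 8 fragments over the metastasis DMSO libraries. Cxcl5, Cxcl1 and Il33 changed by 3.41, 2.55 and -3.08 in metastasis lines, and by 0.4, 0.25 and -0.29 in primary lines.

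Matrix genes rose in 9 and fell in 2 of 25 cases, with 10 and 3 adjusted over the list alone (camera adjusted p = 4.56e-07; adjusted p = 0.269 with an estimated correlation). Col12a1 and Thbs1 rose 5.48-fold and 3.22-fold, and the laminin chain Lamb1 was 1.78-fold lower. Proteases and their inhibitors split, with 7 higher and 7 lower of 21 (9 and 7 adjusted over the list alone; camera adjusted p = 0.328). Adamts1 and the membrane protease Mmp14 rose by 2.11 ± 0.10 and 0.62 ± 0.06, and Ctsl fell by 0.98 on the log2 scale. Fibroblast and stellate markers rose in 2 of 9 cases, with 2 adjusted over the list alone (camera adjusted p = 0.264).

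DNA replication transcripts fell by small amounts. Among 24 S phase genes 15 fell and none rose, with 16 adjusted over the list alone (camera adjusted p = 3.23e-07; adjusted p = 0.454 with an estimated correlation). E2f2, Ccne1 and Cdc45 fell by 0.75, 0.54 and 0.42 on the log2 scale. Of 24 genes of G2 and mitosis 5 fell, with 4 adjusted over the list alone (camera adjusted p = 0.0188; adjusted p = 0.622 with an estimated correlation), among them Cdk1, which fell by 0.33. Without M1 this list did not pass (camera adjusted p = 0.0552). Bmf, a pro-apoptotic BH3-only protein, rose 6.23-fold. The whole list of apoptosis regulators had 3 genes higher and 2 lower of 17 (4 and 2 adjusted over the list alone; camera adjusted p = 0.853).

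Metabolic transcripts moved in several ways. Fatty acid oxidation genes rose in 9 and fell in 1 of 14 cases, with 9 and 1 adjusted over the list alone (camera adjusted p = 0.00883; adjusted p = 0.454 with an estimated correlation). Pdk4 and the co-activator Ppargc1a rose by 1.81 ± 0.12 and 0.89 ± 0.15. Glycolysis and hypoxia genes fell in 10 and rose in 2 of 21 cases, with 10 and 3 adjusted over the list alone (camera adjusted p = 0.0443; adjusted p = 0.595 with an estimated correlation). Pkm fell by 0.34 on the log2 scale, and Ndrg1 and Pfkfb3 rose by 0.91 ± 0.13 and 0.73 ± 0.12. Cholesterol synthesis genes rose in 8 of 23 cases, with 15 adjusted over the list alone (camera adjusted p = 0.00733, and adjusted p = 0.595 with an estimated correlation). Among them was Hmgcs1 (0.54 ± 0.09), which changed by 0.12 in primary and 0.95 in metastasis lines. Lysosome genes rose in 12 and fell in 1 of 24 cases, with 12 and 2 adjusted over the list alone (camera adjusted p = 0.0266; adjusted p = 0.622 with an estimated correlation), with Grn at 0.63 ± 0.08 and Lamp2 at 0.45 ± 0.07. Fatty acid synthesis genes rose in 3 of 15 cases, with 7 and 1 lower adjusted over the list alone (camera adjusted p = 0.0443; adjusted p = 0.595 with an estimated correlation). With a line left out, glycolysis genes did not pass without T2 or M2 (camera adjusted p = 0.113 and 0.0707), fatty acid synthesis without T1, T2 or M1 (0.0608, 0.0535 and 0.0998), and lysosome genes without M1 (0.0892).

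Notch pathway genes rose in 5 and fell in 2 of 10 cases, with 7 and 2 adjusted over the list alone (camera adjusted p = 0.0161; adjusted p = 0.269 with an estimated correlation). Hey1 and Dtx4 rose by 1.41 ± 0.23 and 1.37 ± 0.08, and Nrarp fell by 1.89 on the log2 scale. The fitted change of Nrarp was -0.59 in primary and -3.19 in metastasis lines, where few fragments remained with PLX4720. Without T2, T3, M1 or M2 this list did not pass (camera adjusted p = 0.0535, 0.057, 0.0524 and 0.0524). Of the oncofetal liver genes, Igf2bp1 rose by 1.60 ± 0.14 and Hmga2 fell by 1.81. The change of Igf2bp1 was 0.04 in primary and 3.15 in metastasis lines. The list of 11 had 3 higher and 2 lower, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.912). Its camera direction was opposite in sign to the list's median of 0.34.

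Among all genes, on a list or not, the largest increases that went the same way in all 6 lines included the matricellular gene Ccn5 (4.45 ± 0.55), the actin gene Acta1 (4.01 ± 0.23), Lmod1 (3.63 ± 0.34), Myl9 (3.43 ± 0.36), Hpgd, which degrades prostaglandins, and Cyp1b1 (3.05 ± 0.15). Fitted values of Hpgd and Klhl1 over all 6 lines are left out, as they depend on the prior count, since the metastasis lines gave 0 fragments of Hpgd under DMSO and 2 of Klhl1 with PLX4720. Ccn5 and Lmod1 each had 8 fragments over the primary DMSO libraries. Further increases were those of Slc24a3, Adamts5, Itga11 and Spon2. In T2, Itga11 had 6 fragments with either treatment, so its direction there rests on library scaling. Slc24a3 went from 1 to 3 fragments in T3. The largest decreases were those of Cd53 (15.2-fold), Mctp2 (11.4-fold) and Klhl1, with Areg, Sh2d5, Slc14a1, Hao1, Mrc1, Btc, Upp1, Nptx1 and Mcpt8. In total 4496 of 16555 genes passed the threshold, 2393 higher and 2103 lower (edgeR). Of these, 3243 went the same way in all 6 lines. Among all genes tested 25.5% did so, where chance gives 3.13%. Without T1 the count was 2417, and without the cell line as a block it was 18.

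**Figure D3:**
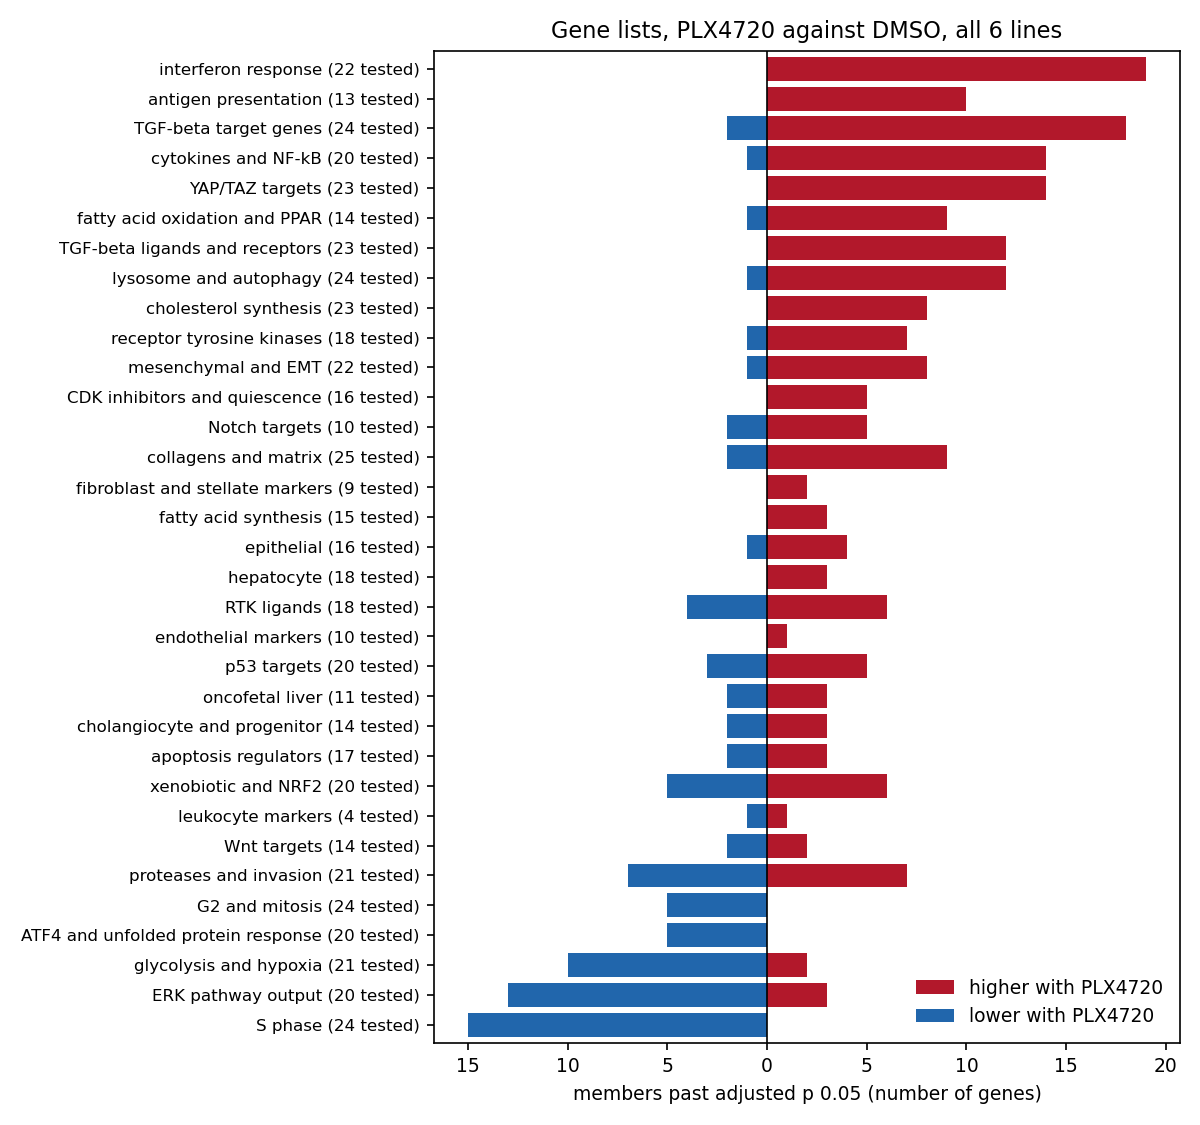
Number of members past an adjusted p of 0.05 (horizontal) for each of the 33 gene lists (vertical), PLX4720 against DMSO over all 6 lines, with members that rose to the right in red and members that fell to the left in blue. The interferon response list has 19 of 22 members to the right, and the ERK output list 13 of 20 to the left.

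In the primary lines alone, PLX4720 lowered ERK-induced transcription factors and raised Tgfb2 and Fgfr3. Etv4 and Etv5 were 4.83-fold and 4.42-fold lower (edgeR adjusted p = 0.00318 and 0.01), and 7 of 20 ERK output genes fell with none higher, with 10 adjusted over the list alone (camera adjusted p = 1.29e-07; adjusted p = 0.408 with an estimated correlation). Fgfr3 rose from 10.9 ± 2.99 to 48.7 ± 18.9 CPM (mean ± SD, n = 3; fitted 4.31-fold, edgeR adjusted p = 0.000966), and Itgb6 rose 3.11-fold. Acta1 (3.66 ± 0.32), Hpgd (3.13 ± 0.27), Sptssb (2.68 ± 0.21), Tgfb2 and Plxnb3 (2.56 ± 0.39) rose most, and Cd53 (20.5-fold), Klhl1 (7.43-fold), Ifi209 (7.07-fold), Stc1 (6.89-fold) and Mctp2 (6.76-fold) fell most. Ifi209 rested on 32 fragments over the DMSO and 4 over the PLX4720 libraries, 24 and 3 of them in T3. Of 22 interferon response genes 3 rose, among them Ddx58 (0.75 ± 0.12), with 5 adjusted over the list alone (camera adjusted p = 0.00519; adjusted p = 0.408 with an estimated correlation). With a line left out, calls in primary lines were lost for Etv5 (adjusted p = 0.0692 without T1), Plxnb3 (0.0555 without T1 and 0.055 without T2), Mctp2 (0.124 without T1 and 0.0687 without T3) and Ddx58 (0.111 without T1 and 0.0739 without T2), and without any 1 of the lines for Cd53 (0.147, 0.0715 and 0.0634 without T1, T2 and T3) and Ifi209 (0.160, 0.0736 and 0.250) (edgeR). In all, 1362 genes passed, 738 higher and 624 lower (edgeR). Counts were 91 without T1, 210 without T2, 340 without T3, 2252 without M1, 2491 with the primary libraries fitted alone, and 1 without the block. T3 is the line whose PLX4720 library holds the mitochondrial share of 3.68%.

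In the metastasis lines alone, most interferon response and many matrix transcripts rose and Wnt7b and Il33 fell. Col1a1 went from 33.8 ± 29.5 to 456 ± 244 CPM and Postn, a matricellular protein, from 14.8 ± 12.4 to 273 ± 163 CPM (mean ± SD, n = 3; fitted 17.6-fold and 23.3-fold, edgeR adjusted p = 0.000124 and 7.86e-05). Matrix genes rose in 13 and fell in 2 of 25 cases, with 15 and 2 adjusted over the list alone (camera adjusted p = 3.20e-13; adjusted p = 0.0949 with an estimated correlation). Fibroblast and stellate markers moved with them, 3 higher and 1 lower of 9, with 4 and 1 adjusted over the list alone (camera adjusted p = 0.00131; adjusted p = 0.143 with an estimated correlation). Interferon response genes rose in 21 of 22 cases, with 21 adjusted over the list alone (camera adjusted p = 3.99e-36, and adjusted p = 0.00622 with an estimated correlation). Ifit3 was 7.24-fold, Gbp2 6.32-fold and Ifit1 4.48-fold higher. Dusp6, an ERK phosphatase, was 3.88-fold lower and Spred3 2.89-fold lower, and 12 of 20 ERK output genes fell with 2 higher, or 13 and 3 adjusted over the list alone (camera adjusted p = 1.85e-06; adjusted p = 0.449 with an estimated correlation). Cxcl1 rose 5.87-fold, and Il33 was 8.45-fold lower (edgeR adjusted p = 4.35e-05 and 4.61e-05). Cholesterol synthesis genes rose in 14 of 23 cases, with 16 adjusted over the list alone (camera adjusted p = 1.85e-06; adjusted p = 0.470 with an estimated correlation), among them Mvk, which rose 2.00-fold. Aoc3 (6.40 ± 0.28), Lmod1 (6.20 ± 0.32), Ccn5 (6.08 ± 0.52) and Igf1 (5.84 ± 0.41) rose most, and Rnf183, Wnt7b and Igsf5 fell by 5.04, 4.80 and 4.52 on the log2 scale, with Chrna1 also among the largest decreases. Aoc3, Lmod1 and Igf1 had 10, 13 and 7 fragments over the DMSO libraries, all 7 of Igf1 in M1, and Rnf183 and Igsf5 had 13 and 5 over the PLX4720 libraries. Megf6 and Ccdc33 also meet the rule, but Megf6 had 1 fragment over the DMSO libraries and Ccdc33 had 0 over the PLX4720 libraries, so that their fitted values depend on the prior count. In all, 3378 genes passed, 1994 higher and 1384 lower (edgeR). Without M2 the count was 1891, with the metastasis libraries fitted alone 2195, and without the block 15.

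Genes that moved in both sites overlapped: 376 rose in both, where independent lists would share 88.9, and 284 fell in both, where they would share 52.2. Another 29 passed in opposite directions, and log2 changes of both sites correlated across genes at Pearson's r = 0.41 and Spearman's rho = 0.468, genes not being independent replicates. With each site fitted alone the counts of 2491 and 2195 genes did not keep the order of 1362 and 3378.

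The difference between the PLX4720 effects of both sites was tested directly. The lists of interferon response, matrix, TGF-β target and cholesterol synthesis genes and of fibroblast and stellate markers differed with the preset correlation, the interferon response alone also with an estimated one, and in each fewer than 10 members passed on their own. For the interferon response the median difference was 1.21 on the log2 scale, with 6 of 22 genes past the threshold and 18 adjusted over the list alone (camera adjusted p = 2.16e-15, and adjusted p = 0.0256 with an estimated correlation). Ifit3 differed by 2.24 ± 0.35 and Stat2 by 1.22 ± 0.21 (edgeR adjusted p = 0.0154 and 0.0214). Matrix genes differed in 9 of 25 cases, with 14 and 1 lower adjusted over the list alone (camera adjusted p = 2.66e-12; adjusted p = 0.0684 with an estimated correlation), among them Col5a1 (1.32 ± 0.16) and Thbs1 (1.27 ± 0.18). TGF-β targets differed in 5 of 24 cases, with 10 adjusted over the list alone (camera adjusted p = 3.33e-11; adjusted p = 0.313 with an estimated correlation), among them Smad6 (1.70 ± 0.23). Cholesterol synthesis genes differed in 4 of 23 cases, with 15 adjusted over the list alone (camera adjusted p = 2.66e-12; adjusted p = 0.345 with an estimated correlation), among them Mvk (1.04 ± 0.18) and Lss (0.85 ± 0.14). Fibroblast and stellate markers had 2 higher and 1 lower of 9, with 4 and 2 adjusted over the list alone (camera adjusted p = 0.0494; adjusted p = 0.345 with an estimated correlation).

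Other genes parted the sites as well. Egfr rose more in metastasis lines, by 1.29 ± 0.20, and Fgfr3 differed by -2.31 ± 0.38, with changes of 2.11 in primary and -0.21 in metastasis lines (edgeR adjusted p = 0.0154 and 0.0181). Aoc3 (7.12 ± 0.55), the small leucine-rich proteoglycans Ogn (5.80 ± 0.77) and Aspn (5.66 ± 0.42), Lmod1 and Krt7 had the largest differences upward among genes whose lines did not overlap between sites, and Cytip (-5.49 ± 0.45), Chrna1 (-5.39 ± 0.77), Rnf183 (-4.56 ± 0.67) and Wnt7b downward, with Ccdc33, which had 0 fragments over the metastasis PLX4720 libraries. Ogn went from 11.3 ± 2.56 to 529 ± 239 CPM in metastasis lines and stood at 0.212 ± 0.0707 and 0.169 ± 0.137 CPM in primary lines (mean ± SD, n = 3). With a line left out, differences lost their call for Ifit3 (adjusted p = 0.0509, 0.0685 and 0.070 without T1, T2 and T3) and Lmod1 (0.058, 0.0846 and 0.0562), for Stat2 (0.0769, 0.101 and 0.0764 without T1, T2 and M3) and Fgfr3 (0.0509, 0.0593 and 0.0611 without T1, T2 and M3), and for Egfr (0.0685 and 0.0579 without T2 and T3) (edgeR). They were lost too for Thbs1 (0.0546 without T2), Rnf183 (0.0611 without M3), Mvk (0.0828, 0.126, 0.0793 and 0.0764 without T1, T2, T3 and M2), Lss (0.0787, 0.106, 0.0507 and 0.0581 without T1, T2, M2 and M3) and Ccdc33 (0.0967, 0.0741, 0.0719, 0.0507 and 0.259 without T1, T2, T3, M2 and M3). In all, 487 genes passed, 306 with the higher change in metastasis lines and 181 with the lower (edgeR). Counts were 160 without T1, 122 without T2, 243 without T3, 798 without M1, 257 without M2 and 295 without M3. Without the block edgeR called 0, with 279 genes at an unadjusted p under 0.05.

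Metastasis against primary lines under DMSO asks how lines of both origins differ without the inhibitor. Most epithelial and liver transcripts that were abundant in primary lines were near 0 in metastasis lines. Of 18 at a primary mean of 10 CPM or more, 17 stood at no more than 0.342% of their primary level, and Tjp1, named after its values were seen, stood at 115 against 249 CPM. Cdh1, the epithelial cadherin, stood at 443 ± 66.7 against 0.41 ± 0.35 CPM, the keratin Krt8 at 2490 ± 636 against 2.06 ± 2.37 CPM, and the hepatocyte transcription factor Hnf4a at 181 ± 60.4 against 0.127 ± 0.111 CPM (mean ± SD, n = 3; edgeR adjusted p = 0.00131, 0.00443 and 0.00157). Apob, the apolipoprotein of liver-secreted particles, stood at 942 ± 293 against 0.939 ± 0.783 CPM. Of 16 epithelial genes 12 were lower and none higher, with 13 adjusted over the list alone (camera adjusted p = 5.88e-17; adjusted p = 0.0694 with an estimated correlation). Hepatocyte genes were lower in 8 of 10 cases, with 8 adjusted over the list alone (camera adjusted p = 1.36e-13, and adjusted p = 0.0694 with an estimated correlation), and cholangiocyte and progenitor genes in 9 of 13, with 9 adjusted over the list alone (camera adjusted p = 6.22e-08, and adjusted p = 0.0694 with an estimated correlation). The other hepatocyte members were not tested. Of 25 with fragments in the primary DMSO libraries, only 7 reached a mean of 10 CPM there. Foxa1 was at least 436-fold and Elf3 at least 1140-fold lower, from a floor of 3 fragments over the group. With a line left out, these bounds were at the lowest 288 (without M3) and 588 (without T1).

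Members of the mesenchymal, matrix and fibroblast lists were higher in the metastasis lines. Col3a1 stood at 1750 ± 433 against 0.821 ± 1.05 CPM and the receptor Pdgfrb at 133 ± 81.2 against 0.0694 ± 0.0807 CPM (mean ± SD, n = 3; edgeR adjusted p = 0.00385 and 0.00215). A4galt and Fgf10 had 0 fragments in the primary lines and were at least 961-fold and 796-fold higher, or 417-fold without M1 and 518-fold without T3, the lowest bounds with a line left out. Fibroblast and stellate markers were higher in 6 of 9 cases, with 8 adjusted over the list alone (camera adjusted p = 7.31e-10; adjusted p = 0.0924 with an estimated correlation), mesenchymal genes in 9 of 20, with 14 adjusted over the list alone (camera adjusted p = 1.55e-08; adjusted p = 0.154 with an estimated correlation). Prrx1, Mmp2 and Twist2 were higher by 7.98 ± 0.80, 7.04 ± 1.08 and 5.12 ± 0.51. Matrix genes were higher in 8 and lower in 4 of 25 cases, with 11 and 4 adjusted over the list alone (camera adjusted p = 6.22e-08; adjusted p = 0.0694 with an estimated correlation), with Bgn, Col6a3 and Col5a2 higher by 9.49 ± 0.65, 9.75 ± 0.49 and 9.14 ± 0.82 and the epithelial laminin Lamb3 lower, at -9.56 ± 1.00.

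Fgf7, Tgfa and some interferon response transcripts differed too. Fgf7, with 7 fragments over the primary DMSO libraries, was higher by 10.04 ± 0.59 and Tgfa lower, at -9.11 ± 0.54 (edgeR adjusted p = 0.00092 for both). Of 17 ligand genes 3 were higher and 3 lower, with 4 and 5 adjusted over the list alone (camera adjusted p = 0.83). Interferon response genes were higher in 9 of 22 cases, with 14 adjusted over the list alone (camera adjusted p = 7.70e-07; adjusted p = 0.473 with an estimated correlation), among them Ifit1 (8.30 ± 1.31) and Gbp2 (5.86 ± 1.01). The Notch ligand Jag1 was 20.8-fold and Hes1 7.97-fold lower, and Notch pathway genes were lower in 5 and higher in 1 of 10 cases, with 7 and 1 adjusted over the list alone (camera adjusted p = 0.000112; adjusted p = 0.0783 with an estimated correlation). Tgfb2 did not pass the threshold (0.18 ± 0.35, adjusted p = 0.808), nor did Tgfb1 (-0.96 ± 0.53, adjusted p = 0.311) or Tgfb3 (1.33 ± 0.84, adjusted p = 0.387). Cdkn2a did not pass with all lines. It passed without M3, the metastasis line that has the transcript (-10.61, edgeR adjusted p = 0.00855), on 5 and 0 fragments in M1 and M2. In all, 1819 of 14992 genes passed, 696 higher and 1123 lower in metastasis lines (edgeR). Counts were 1174 without T2, 901 without M2, 1155 without M3 and 1177 with M2 and M3 summed as 1 line.

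**Figure D4:**
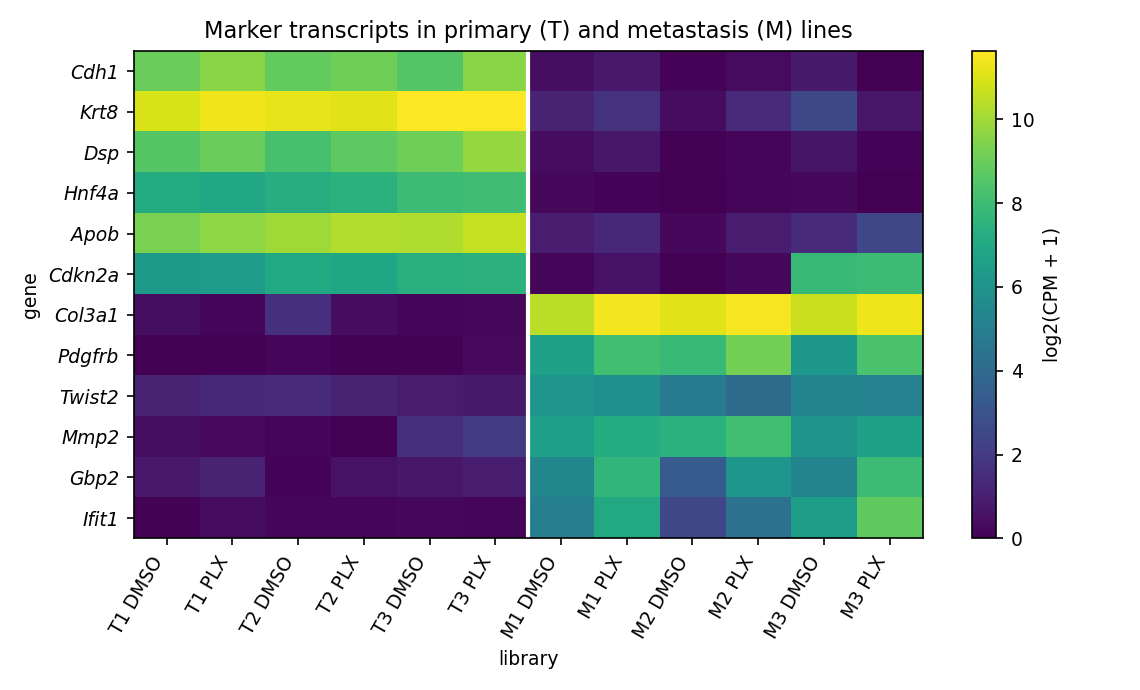
Levels of 12 genes (vertical) in each of the 12 libraries (horizontal), with colour for log2(CPM + 1); a white bar parts primary from metastasis lines. Cdh1, Krt8, Dsp, Hnf4a and Apob are high in primary lines, Col3a1, Pdgfrb, Twist2 and Mmp2 are high in metastasis lines, and Cdkn2a is near 0 in M1 and M2 alone.

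With PLX4720 in both arms the sites differed in similar groups. Krt18 stood at 2170 ± 517 against 1.30 ± 0.173 CPM, Col3a1 at 0.197 ± 0.0979 against 2730 ± 117 CPM and Gbp2 at 0.832 ± 0.343 against 173 ± 94.1 CPM in primary against metastasis lines (mean ± SD, n = 3; edgeR adjusted p = 0.00013, 0.00013 and 0.00187). Epithelial genes were lower in 13 of 16 cases, with 15 adjusted over the list alone, and hepatocyte genes in 8 of 12, with 8 adjusted over the list alone. Both lists passed with the preset correlation (camera adjusted p = 7.87e-25 and 8.42e-13) and with an estimated one (adjusted p = 0.0375 for both). Interferon response genes were higher in 17 of 22 cases, with 22 adjusted over the list alone (camera adjusted p = 1.13e-11; adjusted p = 0.426 with an estimated correlation). Fibroblast and stellate markers were higher in 4 of 9 cases, with 8 adjusted over the list alone (camera adjusted p = 7.54e-16; adjusted p = 0.0667 with an estimated correlation). Cdkn2a did not pass with all lines. It passed without M3, the metastasis line that has the transcript (-8.55, edgeR adjusted p = 0.00583), on 17 and 6 fragments in M1 and M2. Ptx3 had 0 fragments in the primary lines and was at least 6070-fold higher, and Anks4b and Il22ra1 were at least 1550-fold and 1100-fold lower. With a line left out, the lowest bounds were 1750 for Ptx3 (without M2) and 1010 and 714 for Anks4b and Il22ra1 (without M1). In all, 2061 of 15276 genes passed, 858 higher and 1203 lower in metastasis lines (edgeR). Without M2 the count was 1097.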

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

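The splits of the samples and the explanations for the numbers of genes in each site were tested only after those results were seen. The test of the difference between sites was chosen before the data were examined.

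One line stood apart from the other 5 in 2 of 31 groups of values, where about 1 in 20 does so by chance. The change of log2(CPM + 1) of Igf1, a growth factor, was 3.24 in M1 and 0.04 to 1.14 in the other lines. Igf1 went from 7 to 382 fragments in M1, 0 to 39 in M2 and 0 to 16 in M3. From 0 fragments the 1 CPM added before the log sets the change, so a larger fold change in M1 than in M2 or M3 is not shown. The share of mitochondrial fragments rose by 2.98 percentage points in T3 and by 0.0815 to 0.317 in the other lines.

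The PLX4720 effects of both sites differed for 48 of 107 named genes (edgeR, interaction), with 36 values higher and 12 lower in metastasis than in primary lines. Some of these were named because they passed this same test or had a small p in it, and others for large changes. Their share is therefore partly set by the naming, and over all genes 487 of 16555 (2.94%) differed. The log2 difference was above 0 for Aoc3 (7.12), Ogn (5.80), Aspn (5.66), Lmod1 (5.13), Igf1 (4.91), Adamts5 (4.69), Itga11 (4.54), Col1a1 (3.10), Spon2 (2.41), Col12a1 (2.10), Adamts1 (1.79), Col5a1 (1.32) and Thbs1 (1.27). Megf6 (5.68) and Ccdc33 (-6.44) differed too, with fitted values that depend on the prior count, and so did Krt7 (4.83), on 7 fragments over the metastasis DMSO libraries. It was above 0 for Cxcl5 (3.01), Icam1 (2.87), Cxcl1 (2.30), Ifit3 (2.24), Gbp2 (1.87), Stat2 (1.22) and Ifih1 (0.85). Icam1 rested on 8 fragments and Igf1 on 7 over the metastasis DMSO libraries. Changes of log2(CPM + 1) per line overlapped between sites for Icam1 (0.68, 0.04 and 2.27 in M1, M2 and M3), Igf1 (3.24, 1.13 and 0.55) and Megf6 (0.34, 0.89 and 1.57). For Spon2, M3 (0.82) lay below every primary line (1.54 to 2.10). The 1 CPM added before the log shrinks changes of lines near 0, so these overlaps do not show that fold changes overlapped. Spon2 went from 5 to 35 fragments in M3 and from 315 to 1562 in T1. Igf1 went from 0 to 39 in M2, 0 to 16 in M3 and 362 to 896 in T1. Further values above 0 were those of Smad6 (1.70), Amotl2 (1.38), Ccn1 (1.24), Id2 (0.82), Egfr (1.29), Nrg1 (1.13), Spry1 (0.79), Dtx4 (0.78), Slc24a3 (3.60), Igf2bp1 (3.11), Cyp1b1 (2.76), Mvk (1.04), Lss (0.85) and Hmgcs1 (0.82).

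Values were lower in metastasis lines for Cytip (-5.49), Chrna1 (-5.39), Wnt7b (-5), Rnf183 (-4.56), Igsf5 (-4.45), Nptx1 (-3.36), Il33 (-2.79), Sh2d5 (-2.70), Nrarp (-2.59), Fgfr3 (-2.31) and Upp1 (-2.24). Changes per line overlapped for Nrarp (-0.16, -0.26 and -0.75 in M1, M2 and M3, and -0.50 to -0.35 in primary lines) and for Igsf5 in M3 (-0.12). These 2 genes had 4 and 5 fragments over the metastasis PLX4720 libraries. At such levels the 1 CPM added before the log shrinks changes per line, so the overlaps do not show that fold changes overlapped. Sh2d5 and Upp1 fell in each of the 6 lines, by more in metastasis lines.

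Of the 33 gene lists 13 differed between sites (camera, preset correlation), of which the interferon response alone passed with an estimated correlation. The median log2 difference was 1.21 for the interferon response, 1.04 for fibroblast and stellate markers, 0.96 for collagens and matrix, 0.75 for antigen presentation, 0.67 for TGF-β targets, 0.65 for cholesterol synthesis and 0.57 for cytokines and NF-κB. It was 0.45 for mesenchymal genes, 0.28 for fatty acid synthesis, 0.26 for glycolysis and hypoxia, 0.25 for YAP/TAZ targets, -0.16 for lysosome genes and -0.32 for Wnt targets.

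More genes passed in metastasis lines (3378) than in primary lines (1362). Deeper metastasis libraries are argued against, since the median total, in units of 1e+06 fragments, was 35.6 against 36.7 for primary libraries. A spread estimate shared by both sites may account for the order, since with each site fitted alone, on the same genes and scaling, 2280 genes passed in metastasis and 2544 in primary lines, a ratio of 0.896. A larger response of metastasis lines stays open. The median absolute log2 change over all genes tested was 0.2665 in metastasis and 0.2248 in primary lines, a difference that was not tested. With a log2 change of at least 1, 1429 genes passed in metastasis and 482 in primary lines, in the fit with the shared spread. For the interaction, 1 of 10 splits of the lines, the real one, gave as many as 487 genes and the highest other gave 0, and 10 splits are too few for a share under 0.05.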

How the results depend on the processing

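The alternatives below were chosen before the data were examined. The increase of Tgfb2 over all 6 lines passed the threshold under 14 of 14 alternatives, with log2 changes of 2.69 to 2.91 and adjusted p from 4.57e-66 to 0.000325; leaving out a line gave the same range of 2.69 to 2.91. Among 238 other gene results, values kept their direction and side of the threshold 3178 times, lost the threshold 252 times, 131 of them without the cell line as a block, gained it 8 times and changed sign 16 times. Among 198 gene list results these numbers were 416, 139, 18 and 21. None of the 16 and 21 passed the threshold in either fit, and 6 gene results had no value under an alternative. Depth limits genes at or under 3 fragments per group: ratios between groups are bounds, and fitted values depend on the prior count. Without M2 and M3 the lone metastasis line is assumed to vary like the primary lines. Except where fewer lines or a stricter criterion explain it by construction, the cause was not tested.

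Without the cell line as a block, the replicate pairing, the number of genes past the threshold fell from 4496 to 18 over all 6 lines, from 1362 to 1 in primary lines, from 3378 to 15 in metastasis lines and from 487 to 0 for the difference, where edgeR gave 279 genes at an unadjusted p under 0.05. Tgfb1 had a difference of 0.03 without the block. With replicate numbers as a block, metastasis against primary lines gave 1106 genes under DMSO in place of 1819.

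For a log2 change of at least 1, by construction a stricter criterion, 917 genes passed over all 6 lines, 482 in primary and 1429 in metastasis lines. With no filter on low counts 2052 passed in primary lines and 996 for the difference, and Cdkn2a in primary lines stood at 0. DESeq2 gave 920 for the difference, 2974 for metastasis against primary lines under DMSO and 3163 under PLX4720. With the libraries of a site alone, 2491 passed in primary and 2195 in metastasis lines.

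Without M2 and M3, 2710 genes passed in primary lines and 2071 in M1, Tgfb1 changed by 0.13 over the 4 lines left and by 0.51 in M1 with a difference of 0.77, and Cdkn2a in primary lines by -0.01. With M2 and M3 summed as 1 line, 1177 passed under DMSO. Leaving out a line at a time gave 2417 to 4384 genes over all 6 lines, 91 to 2252 in primary lines, 1891 to 3090 in metastasis lines, 122 to 798 for the difference, 901 to 1595 under DMSO and 1097 to 1712 under PLX4720. In primary lines Trp53 then ranged from -0.11 to 0.15, Cdkn2a from -0.03 to 0.10 and Braf from -0.07 to 0.25. The difference between sites ranged from -0.06 to 0.42 for Tgfb2 and from -0.66 to 0.15 for Tgfb1. Cdkn2a in metastasis against primary lines under PLX4720 ranged from -8.55 to 0.07, the lowest without M3, the line that has the transcript.

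With an estimated correlation 1 gene list passed in place of 18, and 13 to 20 passed with a line left out. Over all 6 lines, the adjusted p of lists that turned direction when a line was left out ranged from 0.663 to 0.930 for RTK ligands, 0.544 to 0.896 for cholangiocyte and progenitor genes, 0.721 to 0.927 for oncofetal liver, 0.544 to 0.898 for proteases, 0.620 to 0.999 for Wnt targets, 0.579 to 0.880 for apoptosis regulators and 0.758 to 0.910 for endothelial markers. With fry, adjusted p of lists that turned direction were 0.795 for oncofetal liver, 0.995 for apoptosis regulators and 0.618 for endothelial markers over all 6 lines, 0.902 for endothelial markers in metastasis lines, 0.902 for receptor tyrosine kinases and 0.978 for endothelial markers for the difference, 0.847 for ERK output under DMSO and 0.926 for receptor tyrosine kinases under PLX4720.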

Other observations

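The tests of the splits, of ERK output, of epithelial levels, of Hox genes, of Cdkn2b alone and of Trp53 were chosen only after the results were seen, as were the genes named in this part. The bounds for Mtap and Cdkn2b together were set before their values were seen.

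Some Hox genes and a few other transcription factors, picked after their values were seen, differed between the sites. Of 39 Hox genes 7 stood at 1 CPM or more in every metastasis library and under 0.5 CPM in every primary library, and none the other way round; none of the 7 was among the 11 Hoxa genes. Hoxd8 stood at 30.7 to 107 CPM in metastasis and at most 0.209 CPM in primary libraries, Hoxc8 at 12.7 to 36.6 against at most 0.328, and Hoxc5 at 10.7 to 23.4 against at most 0.378; Hoxc4, Hoxd4, Hoxd9 and Hoxb2 were the others. Tbx18, Tbx15 and Emx2 were higher in each metastasis library than in any primary library, with Tbx18 at 21.4 CPM in M1 and 0.557 CPM in T1 under DMSO. Gata4 and Foxd1 were higher in each primary library, with 27.7 and 18.2 CPM in T1 and 0.0298 and 0 CPM in M1 under DMSO. For any gene, chance parts 3 lines from 3 in this way in 10% of cases.

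Sex chromosome transcripts split the lines across sites. Xist stood at 45.7 to 91.2 CPM in T1, T2 and M1 and at most 0.203 CPM in T3, M2 and M3. The Y-linked Ddx3y stood at 38.6 to 166 CPM in T3, M2 and M3 and at most 0.164 CPM in the others. The names of the deposited tables also give T3, M2 and M3 a common number, so these lines may come from 1 animal. Cdkn2a parted them, with at most 0.182 CPM in M2 against 162 to 175 in T3 and 229 to 254 in M3. With M2 and M3 summed as 1 line, 1177 in place of 1819 genes differed between sites under DMSO.

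Metastasis lines had little of most epithelial and liver transcripts and had fibroblast transcripts. A mixed culture of tumour epithelial cells and fibroblasts is argued against by the median level of epithelial genes in metastasis lines, 0.0927% of that in primary lines for 11 members at 10 CPM or more, a minimum added after the bound was written, and 0.32% for 22 members without it; Tjp1 stood at 46.1% and the other 10 at no more than 0.334%. Stromal cells without mutant BRAF are argued against in M2 and M3, where the median log2 change of ERK output genes was -1.14 and -1.27. Of 20 members 16 and 15 were lower there. The bound for such cells, -0.2 or more, was set after the results were seen and was not measured in cells without mutant BRAF. In M1, at -0.49 with 12 of 20 lower, this explanation stays open. T3 with -0.46 also fell short of the bound of -0.5, and T1 and T2 stood at -0.60 and -0.59. Another cell of origin stays open too. As no line stands in both sites, no count of Hox genes could have favoured it. The count of 7 lay between the bounds of 3 and 10 set for it, and only a count under 3 would have argued against it. A change of epithelial tumour cells, the biological alternative, was not tested further, as no BRAF allele can be read from counts.

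Cdkn2a was near 0 in M1 and M2 alone. Cdkn2b, its neighbour, stood at most at 0.125% of the median of the other 4 lines, so loss or silencing of both together may account for it. A loss that extends to Mtap met neither bound, as Mtap stood at 35.6% to 241% of that median, and its 3121 to 19408 fragments argue against loss of both Mtap copies. Deletion of Cdkn2a in place of Trp53, which the design names, stays open for these lines. Trp53 stood at most at 4.86 CPM in M1 and M2 and at up to 8.55 CPM in other lines. That decides nothing without a line known to keep p53. For M2 such a deletion is hard to hold together with an animal shared with T3 and M3, which had the transcript. Deletion cannot be told apart from silencing in counts.

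Splits of the libraries were compared with the real ones. For PLX4720 over all 6 lines, 1 of 32 exchanges of treatment within lines, the real one, gave as many as 4496 genes. The highest other, the exchange of M1, M2 and M3 together, gave 487 and is the same contrast as the difference between sites. Where a treatment effect is present, the other exchanges move it into the spread, so their low counts do not show what chance gives. Only the rank of the real count is read. The share of 1 in 32 is under 0.05 but is the smallest that 32 exchanges allow, and it takes the lines as independent. Chance is therefore made unlikely but is not excluded. Within primary and within metastasis lines, 1 of 4 exchanges each, the real one, gave as many as 1362 and 3378 genes and the highest other 0. For metastasis against primary lines, 1 of 10 splits, the real one, gave as many as 1819 genes under DMSO, with 0 as the highest other, and as many as 2061 under PLX4720, with 1 as the highest other. These 4 and 10 splits are too few for a share under 0.05.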
